A study of Mus musculus with 9 samples.

How the data were processed

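RNA from 9 cultures of mouse embryonic fibroblasts was hybridised to Affymetrix whole-transcript gene arrays, with 3 arrays for each of the genotypes WT, ΔG and null, per the labels' protocols. The deposited table holds log2 values made by the authors with RMA, which corrects background, normalises by quantiles and summarises the probes of a probe set on the log2 scale. The series text names RMA values from BRB-ArrayTools, and RMA and affy stand in the submitters' processing notes. Versions, the annotation and the genome build are not given in the sources used here. The range of the values and the near-equal array medians were checked, and no further scaling was applied. Whether RMA was run over all 9 arrays at once is not stated. No detection calls were used, and the number of arrays limits the precision.

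The table has 35512 probe sets, of which 1 has no values. A platform annotation table gave exactly 1 gene symbol to 21789 probe sets, several to 1621 and none to 12101; no gene was named from the latter kinds. Of the single symbols, 21698 matched the RefSeq gene table for assembly GRCm38.p6 by gene ID and none was renamed. That table served for names and gene order only, and no coordinates are given because the array's build is unknown. For the 999 genes with several probe sets the one with the highest mean over all arrays was used, leaving 19938 genes.

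Groups came from the genotype in the labels. All 9 arrays entered one limma fit (limma 3.58.1, R 4.3.3) with a mean per genotype, default eBayes without trend, 6 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05 within each comparison. The comparisons were ΔG minus WT, null minus WT and ΔG minus null, with a moderated F test over the 3 genotypes. The labels do not say that the arrays of a group came from separate embryos, so the p-values measure the spread between these samples, which may be technical in part. Array numbers are shared between the groups, but no label says that a number marks a litter, and the fit has no pairing.

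Before the data were examined, 30 gene lists, the tests, the alternatives and the rule for named genes were fixed. The 29 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison, with camera at an estimated correlation and fry beside it. Camera with the estimated correlation called no list in any comparison. With the preset correlation, splits of the arrays into mixed groups called up to 14 lists, so a preset call by itself is weak support. Fry's directional test asks whether the genes of a list move one way and does not compare the list with other genes. The lists cover the cell cycle, E2F, p53, growth, matrix, metabolic, stress and interferon programmes, markers of other cell types, Hox genes, sex-linked genes and the neighbours of Rb1. Beyond those described in the results, lists without a camera call in either comparison against WT were oxidative phosphorylation, amino acid and unfolded protein stress, skeletal muscle, bone and cartilage and adipocyte genes. They had 1, 4, 1, 5 and 5 called members in null minus WT and none in ΔG minus WT, where 5, 1, 0, 4 and 1 had an unadjusted p under 0.05. Names in the lists were matched through synonyms only where the listed name is no current symbol. That restriction was set after a first run, in which Serpina1a had been matched to another gene; it left the camera calls as they were and changed the number of lists past fry in null minus WT. A list's median and camera's direction differed in sign for histone, epithelial, neural, liver, Hox and Rb1-neighbour genes in ΔG minus WT, for germ-line, oxidative phosphorylation, stress, endothelial and neural genes in null minus WT, and for stress, neural and liver genes in ΔG minus null, none of which passed camera there. The 4 measured sex-linked genes were too few to test as a list. Of 23 measured neighbours of Rb1 on chromosome 14, 5 rose and 4 fell in null and none was called in ΔG, where 2 had an unadjusted p under 0.05. Over all genes 18.4% were called in null minus WT, a lower share than among these neighbours.

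Named genes are Rb1, the 8 largest changes in each direction per comparison among called genes whose groups do not overlap, and the 4 members with the lowest p of each list against WT. Predicted genes, clone names, microRNAs, small nucleolar RNAs and odour and pheromone receptors were left out. A gene named after its values were seen is said to be so.

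Chance correlation and overlap from the shared WT arrays were simulated with 100 draws of unchanged groups, with noise independent between genes. The fit was tested on simulated data with the real gene means and spreads, in which 67, 67 and 66 of 19938 genes were changed by a log2 of 0.5, 1 and 2. For ΔG minus WT, 76.1% of genes changed by a log2 of 0.5 and all of those changed by 1 or 2 were called, with 6 false calls. For null minus WT the shares were 88.1%, 98.5% and 100% with 9 false calls, and for ΔG minus null 85.1%, 100% and 100% with 10 false calls. The alternatives covered scaling, a filter on dim genes, the variance prior, array weights, the choice of probe sets, thresholds, a block for the array number, leaving out each array, a covariate for Y-linked expression and the list tests. The Y-linked covariate nearly follows genotype between ΔG and null and varies mainly among the WT arrays, so a call lost with it can come from lower precision. A same-sex comparison, of each genotype with WT arrays of its own sex pattern, and removal of X and Y genes were added after the data were examined. For ΔG minus null the same-sex value is the difference of both such changes, with 1 WT array for null.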

Results

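Gene expression was profiled in primary mouse embryonic fibroblasts of 3 genotypes at Rb1, the gene of the retinoblastoma protein, a repressor of the E2F transcription factors that drive entry into the cell cycle. The cells carried wild-type Rb1 (WT), the ΔG allele, which is mutated at the site through which the protein contacts most E2Fs, or no functional Rb1 (null). Each group held 3 arrays, 9 in all, and the series text describes the cultures as paired by litter without saying which arrays share a litter. Cells were plated in 15 cm dishes and moved 24 h later to medium with 0.1% serum, a condition in which normal fibroblasts leave the cell cycle. Total RNA was measured on whole-transcript arrays as log2 RMA signal. Array medians lay between 6.33 and 6.401, and 19938 genes were tested. Pearson correlations across probe sets were 0.990 to 0.994 within groups and 0.981 to 0.993 between groups. ΔG replicate 3 stood apart from its group. On the first principal component, the axis of largest variation (51.8% of the variance), it lay at −0.30. ΔG replicates 1 and 2 lay at −13.9 and −11.5, WT arrays at −21.3 to −14.7 and null arrays at 24.2 to 27.4. ΔG replicate 3 correlated with null arrays at 0.989 to 0.991 and with WT arrays at 0.989 to 0.993. The other ΔG arrays correlated with null arrays at 0.985 to 0.986. The small number of arrays limits the precision of every value below. Of the genes tested, 3049 differed among the 3 genotypes by limma's moderated F test at an adjusted p of 0.05, and 1678 did so without null replicate 1.

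Rb1 itself was lowest in the null arrays and highest in the ΔG arrays. Its signal was 9.08 ± 0.13 in WT, 9.61 ± 0.13 in ΔG and 8.31 ± 0.23 in null (log2, mean ± SD, n = 3 each). It fell by 0.77 in null against WT (SE 0.12, limma adjusted p = 0.0011). In ΔG it was 0.53 above WT, which did not pass the threshold (SE 0.12, adjusted p = 0.075). The labels do not say which part of the gene the null allele lacks, and probes outside that part would still report RNA, so the signal left in the null arrays does not check the labels. Xist, the RNA that silences one X chromosome in female cells, and the Y-linked genes separated the arrays in another way. All 3 ΔG arrays and WT replicates 1 and 2 had Xist between 4.24 and 4.45 and expressed the Y-linked translation factor Eif2s3y at 9.13 to 9.61. All 3 null arrays and WT replicate 3 had Xist between 11.4 and 12.0 and Eif2s3y at 3.52 to 3.94. Sex pattern and genotype therefore coincided fully between ΔG and null and in part between each of them and WT.

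**Figure D1:**
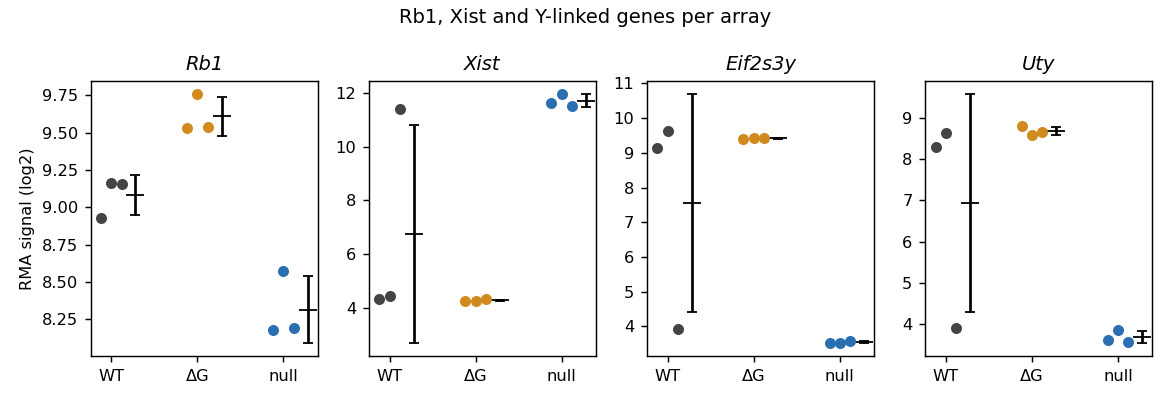
RMA signal (log2) of Rb1, Xist, Eif2s3y and Uty on each array, with points for single arrays and bars for the group mean ± SD (n = 3). Rb1 averages 9.08 in WT, 9.61 in ΔG and 8.31 in null, while WT replicate 3 lies with the null arrays for Xist and the Y-linked genes.

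The first comparison asked which genes respond when the protein loses its common E2F contact while the rest of it is kept. The clearest change in ΔG was a rise of genes for DNA replication. Mcm6, Mcm3, Mcm2 and Mcm4, subunits of the replicative helicase, rose 2.75-fold, 2.73-fold, 2.57-fold and 2.43-fold against WT (log2 changes 1.46, 1.45, 1.36 and 1.28, SE 0.11 to 0.12, n = 3 each, adjusted p = 0.0008 or lower). Prim1 and Pola1, of the primase and polymerase alpha complex, rose 2.50-fold and 2.17-fold, the histone chaperone subunit Chaf1b rose 2.33-fold and Chek1, a checkpoint kinase, 1.99-fold. Of the 56 measured G1/S E2F target genes, 27 rose and none fell, 44 rose when adjusted over the list alone, and the list's median log2 change was 0.61. Its mean signal was 7.79 ± 0.16 in ΔG and 7.15 ± 0.16 in WT (SD over 3 arrays), with no overlap between the groups. The list passed camera with a preset correlation (adjusted p = 3.1e-63) and fry (adjusted p = 0.024), but not camera with an estimated correlation (adjusted p = 0.29 with an estimated correlation).

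Genes of the later cell cycle did not pass singly in ΔG. None of the 51 measured G2/M mitotic genes passed in limma, over all genes or adjusted over the list alone (3 at an unadjusted p under 0.05, and fry's test in either direction gave an adjusted p of 0.50). Their median log2 change was 0.23. Spc25, Ckap2, Tpx2 and Racgap1 had log2 changes of 0.34, 0.24, 0.46 and 0.40 with adjusted p-values of 0.39 to 0.49. Camera with the preset correlation called the list (adjusted p = 2.3e-08), and the adjusted p was 0.71 with an estimated correlation and 0.70 in fry. Without ΔG replicate 3, the array with the highest mitotic signal of its group, the median was 0.017 and camera no longer called it (adjusted p = 0.50). The median was 0.42, 0.12 and 0.14 without WT replicate 1, 2 or 3 and 0.37 without ΔG replicate 2. Within the RB and E2F family of 13 measured genes, Rbl1, which encodes the related pocket protein p107, rose 2.41-fold, and Tfdp1, the dimerisation partner of E2Fs, rose 1.45-fold (adjusted p = 0.0013 and 0.015). No other member was called, 4 rose when adjusted over the list alone, and the list's median was 0.23 (camera adjusted p = 6.2e-05, adjusted p = 0.52 with an estimated correlation), or 0.14 without WT replicate 1. Tfdp1 was no longer called without WT replicate 2 or ΔG replicate 1 (adjusted p = 0.059 and 0.068). Of 13 G1 cyclins, kinases and inhibitors, Cdk2 rose 1.51-fold (adjusted p = 0.0096, or 0.056 without WT replicate 2), and 2 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.062). The replication-dependent histone genes held no called member among 22 in limma, with 4 lower at an unadjusted p under 0.05 and 3 lower when adjusted over the list alone. Their median was 0.066 and their mean 0.0026, while camera's direction was down (adjusted p = 0.73). Without ΔG replicate 3 the histone median was −0.13 and camera called the list (adjusted p = 0.0069).

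Genes outside the cell cycle lists changed in ΔG as well. In all, 162 genes passed, 120 higher and 42 lower, and 16 of the higher and 3 of the lower changed at least 2-fold. Among those that fell were Nmbr, a neuromedin B receptor, 2.70-fold lower, Igfbp2, a binding protein of insulin-like growth factors, 2.51-fold lower, and Tnfrsf21, a death receptor, 2.02-fold lower (adjusted p = 0.017, 0.033 and 0.0026). Gpm6a, Ccdc85a, Ptprq, Slitrk3 and Entpd4 fell by 0.98, 0.97, 0.96, 0.91 and 0.84 on the log2 scale. Nmbr, Igfbp2, Gpm6a and Slitrk3 lost their calls without any one of WT replicates 1 and 2 and ΔG replicates 1 and 2, at adjusted p-values up to 0.097, 0.15, 0.15 and 0.15, and Ptprq without WT replicate 2 or ΔG replicate 2 (0.057 and 0.0503). Igfbp2, Gpm6a and Slitrk3 lost theirs without null replicate 1 as well (0.059, 0.062 and 0.066) and without null replicate 3 (0.0502, 0.057 and 0.059), Gpm6a without ΔG replicate 3 (0.062) and Slitrk3 without WT replicate 3 (0.066). With the mean of the Y-linked genes as a covariate Igfbp2 and Slitrk3 were not called either (log2 changes −1.42 and −0.93, adjusted p = 0.055 and 0.078). Stag3, a meiotic cohesin subunit among the germ-line genes that somatic cells silence, rose 1.55-fold, and Ifit2, an interferon-stimulated gene, rose 1.47-fold (adjusted p = 0.019 and 0.011). These were the only called members of lists of 14 and 24 genes. Stag3 was no longer called without WT replicate 1 or ΔG replicate 2 (adjusted p = 0.066 and 0.078), nor Ifit2 without WT replicate 2 (adjusted p = 0.060). The p53 target genes, the TGF-beta and BMP response genes and the smooth muscle contractile genes passed camera with medians of 0.15, 0.039 and 0.21, and the interferon-stimulated genes with a median of −0.12 (adjusted p = 0.0011, 0.034, 0.0036 and 0.032). With an estimated correlation their adjusted p-values were 0.71, 0.70, 0.71 and 0.71. The TGF-beta, smooth muscle and interferon lists were no longer called without WT replicate 3 (medians 0.027, 0.071 and −0.097), and the interferon list also without WT replicate 1 or ΔG replicate 1 (−0.13 and −0.11). The TGF-beta list lost its call with repeated quantile normalisation and with the dimmest genes removed (adjusted p = 0.057 and 0.084), and the interferon list with median centring and with that removal (0.058 and 0.084). The TGF-beta median was 0.082 and 0.10 without WT replicate 1 or 2 and 0.016 without ΔG replicate 2, the smooth muscle median 0.10 and 0.13 without ΔG replicate 1 or 2, and the interferon median −0.20 without WT replicate 2. Macrophage and leukocyte markers also passed camera, with a median of 0.56 and no called member in limma, 2 of 16 being higher at an unadjusted p under 0.05 (camera adjusted p = 2.4e-05, adjusted p = 0.71 with an estimated correlation). Their mean signal was 7.39, 6.78 and 5.90 on ΔG replicates 1, 2 and 3, against 6.72, 6.24 and 5.50 on WT replicates 1, 2 and 3, and without ΔG replicate 1 camera no longer called them (median 0.20, adjusted p = 0.084). The median was 0.22 without WT replicate 3, 0.85 without WT replicate 1 and 1.05 without ΔG replicate 3. Matrix, immediate early, cholesterol, glycolysis, inflammatory and E2F-linked apoptosis genes did not pass camera in ΔG (adjusted p = 0.062 to 0.71) and held no called member in limma, with 4, 5, 2, 5, 7 and 1 members at an unadjusted p under 0.05. Without ΔG replicate 3 camera called the cholesterol list, with a median of −0.12 (adjusted p = 0.042).

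Of the 162 calls, all had groups that did not overlap, as did 3652 of the 3678 calls in null minus WT and 1727 of the 1737 in ΔG minus null. Passing the threshold itself selects for such separation, so it adds no support. The 10% that chance gives holds only for genes not selected by a call. The count of 162 moved to 62 without WT replicate 2, 70 without ΔG replicate 2, 83 without ΔG replicate 1, 91 without null replicate 1 and 252 without ΔG replicate 3. Against the WT arrays of the same sex pattern alone, an alternative chosen after seeing the data, 129 genes passed, of which 102 were shared with the 162.

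The second comparison set cells without Rb1 against WT, where genes of DNA replication and genes of mitosis both rose. Of the 56 G1/S E2F target genes 54 rose, also when adjusted over the list alone, with a median log2 change of 1.18. Prim1 rose 5.14-fold, Mcm6 4.46-fold, Pola1 4.01-fold, Chaf1b 3.88-fold, Pole2, a subunit of polymerase epsilon, 3.77-fold, and Mcm3 and Mcm2 3.74-fold and 3.73-fold (log2 changes 1.90 to 2.36, SE 0.11 to 0.15, n = 3 each, adjusted p = 1.5e-05 or lower). All 51 measured G2/M mitotic genes rose, over all genes and adjusted over the list alone, with a median of 0.96. Among them Kif23, a kinesin of cytokinesis, rose 2.44-fold, Spc25, of the kinetochore, 2.11-fold, the kinase Melk 2.09-fold and Ckap2 1.72-fold. Kif23 missed the threshold with the mean of the Y-linked genes as a covariate (log2 change 1.16 against 1.29, adjusted p = 0.052). Camera with the preset correlation gave adjusted p-values of 4.6e-52 for the G1/S list and 9.1e-27 for the G2/M list, and fry gave 0.00085 and 0.036. The adjusted p-values were 0.44 and 0.46 with an estimated correlation.

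**Figure D2:**
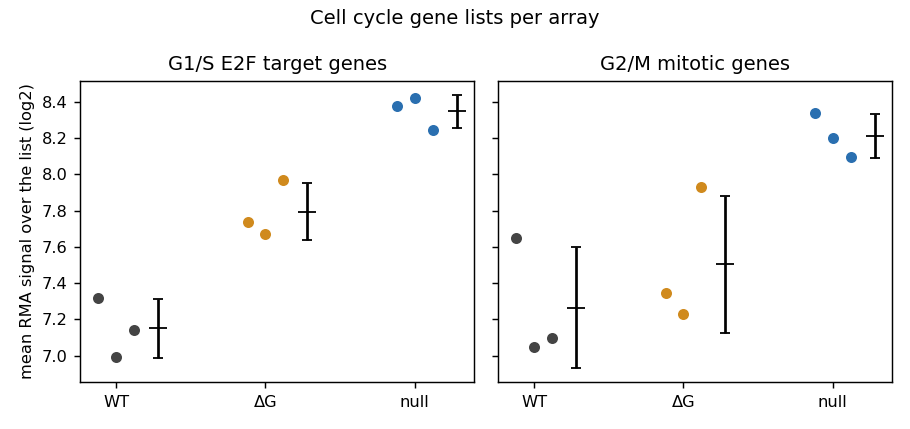
Mean RMA signal (log2) over the 56 G1/S E2F target genes and the 51 G2/M mitotic genes on each array, with points for arrays and bars for the group mean ± SD (n = 3). The G1/S means are 7.15 in WT, 7.79 in ΔG and 8.35 in null, and the G2/M means are 7.27, 7.50 and 8.21.

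Some regulators of the cycle also changed in null cells, in both directions. Of 13 RB and E2F family genes, 5 rose and Rb1 fell, 6 and 1 when adjusted over the list alone. Rbl1 rose 3.29-fold, the repressor E2Fs E2f8 and E2f7 2.98-fold and 2.17-fold, and Tfdp1 1.69-fold (camera adjusted p = 0.0020, adjusted p = 0.46 with an estimated correlation). Of 13 G1 cyclins, kinases and inhibitors, 4 rose and 3 fell, or 5 and 4 when adjusted over the list alone. The kinase Cdk2 rose 2.18-fold, the CDK4 and CDK6 inhibitor Cdkn2c 2.83-fold and the ubiquitin ligase subunit Skp2 1.75-fold, while the inhibitor Cdkn1c was 1.76-fold lower. That list did not pass camera (adjusted p = 0.079), and Cdkn1c was no longer called against the WT array with high Xist alone (log2 change −0.67, against −0.82 with all WT arrays). In comparisons with that 1 array its spread was taken to be that of the other groups, so a call lost there can come from lower precision. Of 22 replication-dependent histone genes 11 rose and 3 fell, with the same numbers over the list alone. H2ac4 rose 3.26-fold, while H2bc4, H3c4 and H3c15 were 2.55-fold, 2.15-fold and 1.68-fold lower, and histone genes are near-identical copies whose probes are uncertain. H3c4 was not called with the mean of the Y-linked genes as a covariate (log2 change −0.84 against −1.11, adjusted p = 0.060). The list's median was 0.37 (camera adjusted p = 0.013, adjusted p = 0.65 with an estimated correlation), and camera no longer called it without null replicate 1 (median 0.36, adjusted p = 0.067). The median was 0.81 with the dimmest genes removed and 0.57 against the WT array with high Xist alone. Casp8 and Bid, both apoptosis genes linked to E2F, rose 1.28-fold each among 12 such genes, and Stag3 and Smc1b, meiotic cohesin subunits, rose 1.55-fold and 1.22-fold among 14 germ-line genes. Neither list passed camera (adjusted p = 0.072 and 0.94), and Bid and Smc1b lost their call in 9 of 19 and 9 of 18 alternatives, among them the omission of any one WT array (adjusted p up to 0.10 and 0.12) and of null replicate 1 (0.15 and 0.074).

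Some genes of the fibroblast matrix and of the contractile apparatus were lower in null cells. Of 30 measured extracellular matrix genes 15 fell and 2 rose, or 19 and 2 when adjusted over the list alone, with a median log2 change of −0.46. The proteoglycan gene Dcn was 2.60-fold lower, Thbs2 1.94-fold, the collagenase Mmp13 2.89-fold and Col3a1, of fibrillar collagen, fell by 0.59 on the log2 scale. Dpt, which encodes the matrix protein dermatopontin, was 13.9-fold lower. Of 14 smooth muscle contractile genes 5 fell and none rose, over all genes and adjusted over the list alone, with a median of −0.29. Mylk, Cnn1, Myh11 and Tpm1 were 1.82-fold, 1.73-fold, 2.01-fold and 1.31-fold lower (adjusted p = 0.0035 to 0.034), and Cnn1, Myh11 and Tpm1 were no longer called without WT replicate 1 (0.073, 0.054 and 0.067), WT replicate 2 (0.11, 0.10 and 0.13) or null replicate 3 (0.071, 0.10 and 0.12). Without null replicate 1 Myh11 and Tpm1 (0.057 and 0.10) and without null replicate 2 Myh11 (0.060) lost their calls too. Camera adjusted p-values were 8.3e-07 and 0.0055, 0.46 and 0.61 with an estimated correlation, and 0.036 and 0.18 in fry. WT replicate 3, the array with high Xist, already lay below the other WT arrays in both lists, by medians of −0.40 and −0.36. Against that array alone the matrix median was −0.18 with 5 called genes, and the smooth muscle list had a median of −0.11 and was no longer called (adjusted p = 0.46), nor were Col3a1 and any of the 4 contractile genes named. There Col3a1, Mylk, Cnn1, Myh11 and Tpm1 had log2 changes of −0.50, −0.64, −0.44, −0.50 and −0.26, against −0.59, −0.87, −0.79, −1.01 and −0.39 with all WT arrays. With the mean of the Y-linked genes as a covariate Mmp13 and Thbs2 lost their calls as well, with log2 changes of −0.80 and −0.51 against −1.53 and −0.95 (adjusted p = 0.080 and 0.059). The smooth muscle median was −0.19 without WT replicate 2, −0.48 without WT replicate 3 and −0.13 without null replicate 3.

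Some members of several metabolic and signalling lists rose in null cells, while most members of each list did not pass. Of 17 cholesterol synthesis genes 7 rose and none fell, 13 when adjusted over the list alone, with Stard4 2.19-fold, Lss 1.69-fold, Idi1 1.65-fold and Hmgcs1 1.43-fold higher. Of 17 glycolysis genes 7 rose and 1 fell, 8 and 2 when adjusted over the list alone, among them the lactate exporter Slc16a3, 1.73-fold, Pfkl, 1.58-fold, Tpi1, 1.53-fold, and Ldha, 1.45-fold higher. Of 25 immediate early and serum response genes 7 rose, also over the list alone, led by Fosl1 at 2.36-fold and Klf10 at 1.75-fold. Of 24 interferon-stimulated genes 8 rose and 1 fell, 9 and 1 when adjusted over the list alone, with Usp18 1.76-fold, Ifit2 1.63-fold, Ifih1 1.56-fold and Irf7 1.35-fold higher. The medians of the 4 lists were 0.34, 0.22, 0.31 and 0.28 and their camera adjusted p-values 2.3e-06, 0.0029, 0.00024 and 0.00013. With an estimated correlation the adjusted p-values were 0.54, 0.54, 0.61 and 0.46, and in fry 0.083, 0.048, 0.16 and 0.048. Without null replicate 2 the immediate early median was 0.19. Lss, Idi1, Hmgcs1, Ldha, Usp18 and Ifih1 were no longer called against the WT array with high Xist alone, where the glycolysis median was 0.37. Their log2 changes there were 0.74, 0.54, 0.48, 0.52, 0.51 and 0.40, against 0.76, 0.72, 0.52, 0.54, 0.82 and 0.64 with all WT arrays. With the mean of the Y-linked genes as a covariate Klf10, Stard4 and Irf7 lost their calls too, with log2 changes of 0.51, 1.02 and 0.41 against 0.81, 1.13 and 0.43 (adjusted p = 0.056, 0.065 and 0.062). Id1 and Id3, targets of BMP signalling, rose 1.68-fold and 1.38-fold, within a list of 15 genes of which 4 rose and 1 fell, 6 and 1 when adjusted over the list alone (median 0.0030, camera adjusted p = 0.13). Among 25 inflammatory and senescence-secreted factors 2 rose and 5 fell, 3 and 7 when adjusted over the list alone, with Igfbp3 2.56-fold, Ccl2 2.12-fold and Ccl7 1.77-fold lower and Cxcl1 1.43-fold higher (camera adjusted p = 0.34), and Ccl2 and Ccl7 were no longer called against the WT array with high Xist alone (log2 changes −0.96 and −0.60, against −1.08 and −0.83).

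**Figure D3:**
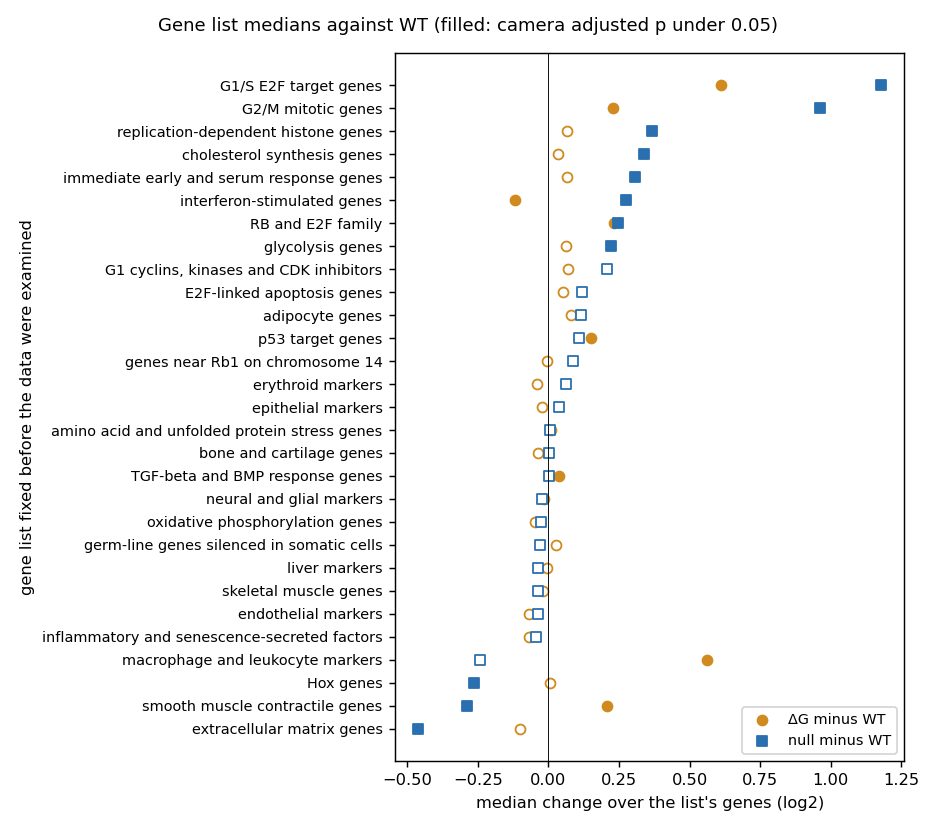
Median log2 change over the measured genes of each fixed list, with circles for ΔG minus WT and squares for null minus WT, filled where camera with the preset correlation passed. The G1/S list lies at 0.61 in ΔG and 1.18 in null, and the matrix list at −0.10 and −0.46.

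Hox genes, which record the position a cell came from along the body and limb axes, changed in both directions in null cells. Of 37 measured genes 5 rose and 15 fell, 6 and 15 when adjusted over the list alone, and the list's median was −0.26 (camera adjusted p = 0.0025, adjusted p = 0.46 with an estimated correlation). The genes that fell included Hoxd4, 3.11-fold, Hoxd8, 2.50-fold, Hoxc8, 2.16-fold, and Hoxb9, 1.70-fold lower, and all 15 belonged to paralog groups 1 to 9. Those that rose were Hoxa11, Hoxd10, Hoxd11, Hoxd12 and Hoxd13, by log2 changes of 0.45, 0.80, 0.71, 1.08 and 1.21, named here after their values were seen. No Hox gene was called in ΔG against WT in limma, with 4 of 37 at an unadjusted p under 0.05, and fry gave the list an adjusted p of 0.85. Against the WT array with high Xist alone the list's median in null was −0.11.

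**Figure D4:**
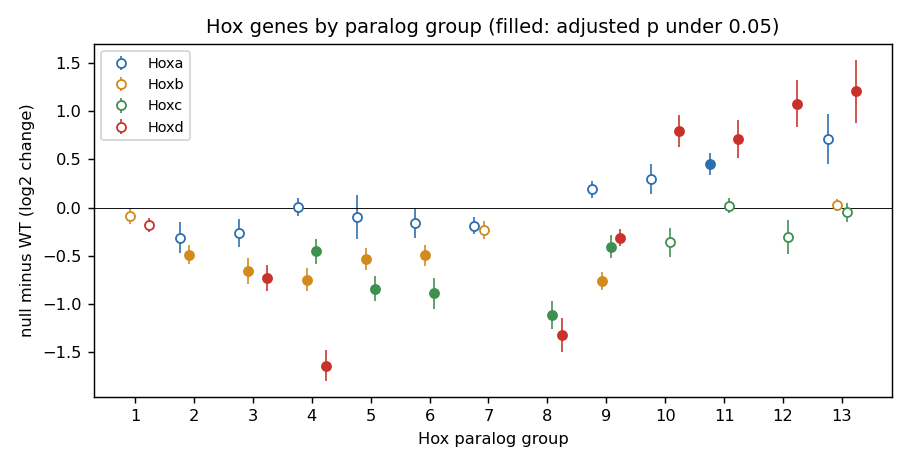
Log2 change, null minus WT, of each measured Hox gene by paralog group, with bars for the standard error and filled points at an adjusted p under 0.05. The 15 called genes of groups 1 to 9 lie below 0 and the 5 called genes of groups 10 to 13 above it.

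In all, 3678 genes passed in null against WT, 1670 higher and 2008 lower, and 218 and 162 of these changed at least 2-fold. With repeated quantile normalisation the balance turned, with 1998 higher and 1854 lower, and with median centring it was 1652 and 2058. Apart from Xist and the Y-linked genes, the largest changes among the named genes were in Glp1r, a receptor for an incretin hormone, 5.30-fold higher, and in AI506816, a transcript without an assigned function, 29.5-fold lower. The protease inhibitor Serpina3n was 9.51-fold, the prolactin family member Prl3a1 5.46-fold and the phospholipase Pla2g7 4.82-fold lower. Prl3a1 was not called with the mean of the Y-linked genes as a covariate (log2 change −2.17 against −2.45, adjusted p = 0.077). Markers of erythroid, endothelial, epithelial, neural and liver cells did not pass camera in null or ΔG against WT (adjusted p = 0.38 to 0.97), and Krt19, a keratin gene, rose 2.78-fold. Emcn, among the endothelial markers, was called lower in null (log2 change −0.81) but lost its call in 14 of 18 alternatives. Macrophage and leukocyte markers had a median of −0.24 and no member called in limma or at an unadjusted p under 0.05 (camera adjusted p = 0.45, fry adjusted p = 0.77). Of 20 p53 target genes, Perp and Tnfrsf10b rose 1.60-fold and 1.30-fold and Xpc was 1.27-fold lower, with the same numbers over the list alone (camera adjusted p = 0.072). Perp and Tnfrsf10b lost their calls without WT replicate 1, WT replicate 2, null replicate 1 or null replicate 2 (adjusted p up to 0.12 and 0.14), and Tnfrsf10b also without WT replicate 3 or ΔG replicate 2 (0.14 and 0.052). Against the WT array with high Xist alone Perp and Xpc had log2 changes of 0.45 and −0.40, against 0.68 and −0.35, and were not called (adjusted p = 0.37 and 0.053), nor were they with the mean of the Y-linked genes as a covariate (0.40 and 0.064). The count was 1580 with the mean of the Y-linked genes as a covariate and 2010 against the WT array with high Xist alone, of which 1760 were among the 3678.

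The third comparison set ΔG directly against null. G1/S genes were lower in ΔG, 44 of 56 called, 53 when adjusted over the list alone, with a median of −0.54. G2/M genes were lower too, 23 of 51 called, all 51 when adjusted over the list alone, with a median of −0.70. Camera adjusted p-values were 7.8e-30 and 7.9e-23, and 0.54 for both with an estimated correlation. Of 30 matrix genes 8 were higher in ΔG and none lower, and of 14 contractile genes 6 were higher and none lower (medians 0.41 and 0.51, camera adjusted p = 4.4e-07 and 2.6e-07). For both lists the adjusted p was 0.54 with an estimated correlation and 0.078 in fry. The matrix median was 0.26 with repeated quantile normalisation and −0.039, reversed and not called, when each genotype was set against WT arrays of its own sex pattern (adjusted p = 0.89). Of 24 interferon-stimulated genes 8 were lower and none higher (median −0.31, camera adjusted p = 5.3e-09, adjusted p = 0.54 with an estimated correlation). Cholesterol synthesis, histone, immediate early and glycolysis genes had medians of −0.44, −0.32, −0.21 and −0.15 and passed camera (adjusted p = 3.3e-07, 0.0012, 0.0026 and 0.0013), with adjusted p = 0.54, 0.54, 0.59 and 0.54 with an estimated correlation. In these 4 lists 3, 3, 5 and 5 genes were lower and 1 histone gene higher, or 13, 12, 6 and 7 lower and 2 histone genes higher when adjusted over the list alone. The histone median was −0.63 with the dimmest genes removed. The histone list was no longer called without ΔG replicate 2 (median −0.23), nor the immediate early list without ΔG replicate 2 or null replicate 2 (−0.13 and −0.094). The cholesterol median was −0.25 without ΔG replicate 1, the glycolysis median −0.084 without null replicate 2 and the immediate early median −0.31 without ΔG replicate 3. Adjusted over the list alone, 12 matrix genes were higher and 1 lower, 11 contractile genes higher and 15 interferon genes lower. Of 37 Hox genes 14 were higher and 8 lower in ΔG, 19 and 8 when adjusted over the list alone (median 0.28, camera adjusted p = 0.00030, adjusted p = 0.54 with an estimated correlation). The Hox median was 0.49 with the dimmest genes removed. Macrophage and leukocyte markers had a median of 0.79 and no called member in limma, 8 of 16 being higher at an unadjusted p under 0.05 (camera adjusted p = 2.6e-05, adjusted p = 0.54 with an estimated correlation). The macrophage median was 0.40 without ΔG replicate 1 and 1.18 without ΔG replicate 3.

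Among single genes, Serpina3n was 12.6-fold, AI506816 39.6-fold, Dpt 6.95-fold and Trak1, an adaptor of mitochondrial transport, 4.05-fold higher in ΔG than in null. Glp1r was 4.78-fold, Coch, an extracellular protein gene of the inner ear, 2.96-fold, Hoxd13 3.16-fold and Glo1, a methylglyoxal-detoxifying enzyme, 2.94-fold lower. In all, 1737 genes passed, 886 higher and 851 lower in ΔG. The balance turned with repeated quantile normalisation, to 821 higher and 1091 lower, and with median centring, to 844 and 950. ΔG and null arrays differ fully in sex pattern, so a Y-linked covariate nearly follows this comparison, and a call lost with it can come from lower precision. With the Y-linked mean as a covariate the count was 53. It was 146 when each genotype was set against WT arrays of its own pattern, where the matrix median reversed to −0.039 and the macrophage median to −0.15, the smooth muscle and immediate early lists were no longer called (medians 0.18 and −0.075) and Dpt, Glp1r, Coch and Hoxd13 lost their calls. Their log2 changes of 3.001, −2.35, −1.59 and −1.99 there were no smaller than the 2.80, −2.26, −1.56 and −1.66 with all WT arrays. The glycolysis, histone and Hox medians there were −0.31, −0.58 and 0.17, all still called. Without ΔG replicate 1, without null replicate 1 and without ΔG replicate 2 the count was 762, 847 and 885.

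Most genes called in ΔG were also called in null in the same direction. Of the 120 genes higher in ΔG, 112 were higher in null and 1 was lower, where independent lists of these sizes would share 10.1. Of the 42 lower genes 38 were lower in null, against 4.23. Of these 150 shared genes 134 had the larger change in null, 78 differed between ΔG and null in the direct test, and the median ratio of the log2 changes, ΔG over null, was 0.66. Across all genes, which are not independent replicates, the log2 changes of both comparisons had a Pearson correlation of 0.54 and a covariance of 0.028. Without ΔG replicate 3 the correlation was 0.36. In 100 simulations of unchanged groups, with noise drawn independently for each gene, both comparisons shared their WT arrays. The correlation there was 0.46 to 0.53, a range that may be too narrow for genes that move together. The mean covariance was 0.0054 and the median number of shared calls 0. Unchanged groups give almost no calls, so that number does not measure what shared WT arrays add to an overlap of real changes. The WT arrays are too few to be split between the comparisons, and part of the excess overlap may come from sharing them.

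**Figure D5:**
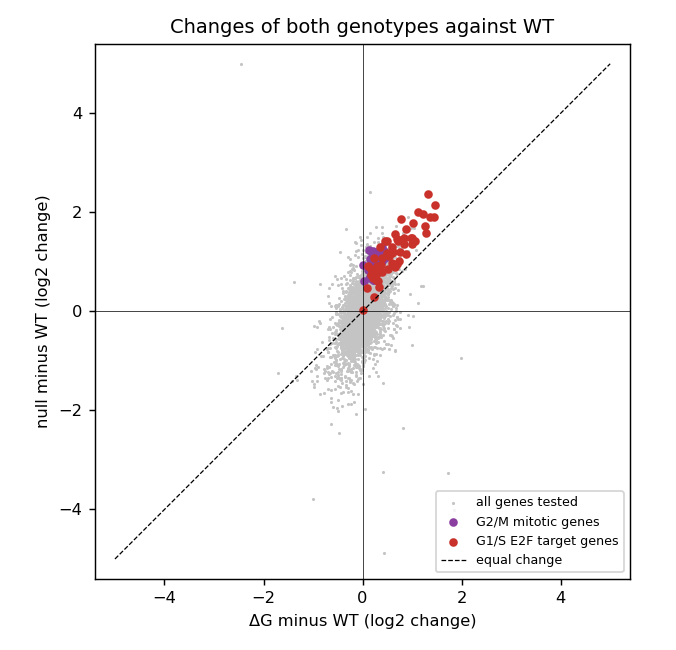
Log2 change of each of the 19938 genes in ΔG minus WT (horizontal) and null minus WT (vertical), with G1/S E2F target genes and G2/M mitotic genes coloured and a dashed line of equal change. The medians are 0.61 and 1.18 for G1/S genes and 0.23 and 0.96 for G2/M genes.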

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

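The tests within one sex pattern, of the Hox index by sex and of the segment around Glo1 were chosen after the results were seen, and the splits of the arrays were written first. The limb gene test was written before it was run, but its gene list is not among the fixed lists and was chosen after the values were seen. In 4 gene lists the medians of ΔG and null lay on opposite sides of WT and differed in the direct test by camera with the preset correlation, but not with an estimated one (each adjusted p = 0.54). The median log2 differences, ΔG minus null, were 0.51 for smooth muscle contractile genes, −0.31 for interferon-stimulated genes, 0.79 for macrophage and leukocyte markers and 0.28 for Hox genes, whose ΔG minus WT median was near 0 (0.0047). With each genotype set against WT arrays of its own sex pattern, the macrophage difference reversed to −0.15 and the smooth muscle one was 0.18. Neither was called there, where null had 1 WT array to be set against. The macrophage difference was 0.40 and 1.18 without ΔG replicate 1 or 3. Probe sets with no or several gene symbols, which the comparisons above do not use, also held calls among 13722. These were 14 in ΔG minus WT (0.10%), 660 in null minus WT (4.81%) and 217 in ΔG minus null (1.58%). In the same fit over all probe sets, those with 1 symbol were called more often, at 0.25%, 13.6% and 4.99%.

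Of the 10 splits of the 6 arrays in each pairwise comparison, the real one gave 162, 3678 and 1737 changed genes (ΔG minus WT, null minus WT, ΔG minus null) and the highest of the others 3, 0 and 0. For the G1/S median the real sizes were 0.61, 1.18 and 0.54 and the highest others 0.40, 0.56 and 0.36, and for both results 1 split of 10, the real one, was as large. For the number of lists past camera, the real 8, 11 and 11 were reached or passed by 6, 4 and 4 of the splits, with highest others of 11, 14 and 14. With 10 splits no share under 0.05 can be had. For the number of lists the outcome is plainer, as several mixed splits called as many. That number does not set the real groups apart, and passing camera with the preset correlation is weak support by itself. For any difference among the genotypes 1 of 100 drawn splits of the 9 arrays, the real one with 3049 genes, was as large, the highest other being 2241. That argues against chance for that count, but it does not separate genotype from sex pattern, which the real split follows in part. The correlation of 0.54 between both comparisons against WT was reached by 54 of 100 drawn splits, up to 0.94. Such splits can put null arrays into the control group that both comparisons share, so they decide nothing about chance and do not exclude it. Simulated unchanged groups gave a correlation of at most 0.53, and a covariance of at most 0.0060 against 0.028 observed. Their noise was independent between genes, so both limits may be too low for genes that move together. They do not judge the 0.54, which was 0.36 without ΔG replicate 3.

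The E2F gene changes go with sex patterns in part, since null arrays have high Xist and ΔG arrays Y-linked expression. Among Y-expressing arrays alone, 3 ΔG against 2 WT, the G1/S median was 0.62 with 24 called genes, which argues against sex as the source in ΔG. Against the single WT array with high Xist the null medians were 1.14 for G1/S and 1.16 for G2/M genes, but 1 array excludes nothing, so sex and genotype cannot be told apart there. The high-Xist WT array differed from the other WT arrays by medians of −0.027 for G1/S and −0.24 for G2/M genes. For matrix and smooth muscle genes the medians were −0.40 and −0.36. With 1 array against 2, differences of single genes cannot be judged. Loss of Rb1 remains an open explanation, untested apart from sex.

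The rise of 5 of 12 Hox genes of groups 10 to 13 and fall of 15 of 25 of groups 1 to 9 in null, with Hoxc10 and Hoxc12 lower but not called (−0.36 and −0.31), may reflect where in the embryo the fibroblasts came from. An index, the mean of the 12 measured genes of groups 10 to 13 minus that of the 25 of groups 1 to 9, was 0.17 ± 0.068 in null, −0.72 ± 0.17 in WT and −1.002 ± 0.52 in ΔG (SD, n = 3). Of 15 limb positional genes other than Hox, Tbx4, Jag2, Pitx1 and Tbx5 rose and Shox2 fell in null, named here after their values were seen. Of the 15, 33.3% were called against 18.4% of all genes (one-sided Fisher exact p = 0.13), which leaves body region open. Camera over 4 lists chosen after the values were seen gave the limb list adjusted p-values of 0.10 in null minus WT and 0.0028, lower, in ΔG minus null. With an estimated correlation camera gave 0.14 and 0.025. A list chosen that way does not settle the question. The WT array with high Xist had an index of −0.84, but it is 1 array, and sex cannot be told apart from genotype there. The index was −1.31, −1.29 and −0.40 on ΔG replicates 1, 2 and 3, so replicate 3 stood apart from its group. Genotype stays open as well.

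Glo1 and its neighbours Btbd9, Dnah8 and Glp1r, with no other measured gene between them, were higher on each null array than on every other array. Their log2 changes were 1.41, 0.57, 0.24 and 2.41, the third not called (adjusted p = 0.0503), and 2 of the 10 nearest genes outside were called, Mdga1 higher and Abcg1 lower. A strain variant that copies the segment is a candidate explanation. The signals of Glo1 and Btbd9, the 2 above the median signal on every array, did not rise alike, as their changes differ by 0.84 (standard error 0.12). That difference was visible before the test was chosen, and array signal need not follow copies equally, so a gain of copies stays open. A variant that acts unequally on the genes was not tested, and Dnah8, dim on every array, decides nothing. Glp1r, dim on WT and ΔG arrays, was 7.41 to 8.61 on null arrays, above the median signal of 6.355. Its change of 2.41 (standard error 0.25) was larger than those of Glo1 and Btbd9, under the same limits. Glo1 was 9.26 on the WT array with high Xist, near the other WT arrays, and sex cannot be told apart from genotype with 1 such array.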

How the results depend on the processing

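The same-sex comparison and the removal of X and Y genes were chosen after the data were examined. The G1/S medians kept their direction under all 17 alternatives run for them and passed in 16. With an estimated correlation the medians of 0.61, 1.18 and −0.54 (ΔG minus WT, null minus WT, ΔG minus null) no longer passed, at camera adjusted p-values of 0.29, 0.44 and 0.54, the highest of any alternative, and 0 lists passed in each comparison. That setting estimates how far members move together, but why the calls were lost was not tested. Fry called 1 list in ΔG minus WT and 3 in ΔG minus null. Of the changed genes in ΔG minus WT, null minus WT, ΔG minus null and any difference, the counts were 251, 1972, 1013 and 1603 at an unadjusted p under 0.001 and 89, 1197, 664 and 1280 with a 1.5-fold minimum. Array weights gave 292 in ΔG minus WT, 3697 in ΔG minus null and 4845 for any difference, and counting all probe sets gave 68 in ΔG minus WT; the cause was not tested. The Y-linked covariate gave 1580, 53 and 1358 in null minus WT, ΔG minus null and any difference, and same-sex arrays gave 2010 and 146 in the first pair of these. In same-sex arrays the median standard error of the called genes grew 1.42-fold and 1.82-fold while the median ratio of the log2 changes to the main ones was 1.01 and 1.02, so fewer arrays per contrast go with calls lost there. Leaving out 1 array gave 62 to 252, 2546 to 3895, 762 to 2408 and 1678 to 3659 changed genes, 8 to 11, 11 to 13 and 9 to 13 lists, G1/S medians of 0.52 to 0.70, 1.09 to 1.23 and −0.64 to −0.46, and a correlation of 0.36 to 0.60.

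Values that reversed were these. Without ΔG replicate 3 the histone and cholesterol lists in ΔG minus WT, not called over all arrays, passed with medians of −0.13 and −0.12, and the highest medians with 1 array left out were 0.13 and 0.15. With each genotype set against WT arrays of its own sex pattern, the matrix and macrophage medians in ΔG minus null were −0.039 and −0.15. With the Y-linked covariate, Kdm5d and Xist in ΔG minus null were −0.14 and 0.044, and Uty and Xist in null minus WT 0.10 and −0.15, since the covariate is made of Y-linked genes. A fixed replicate block gave 211, 3777 and 1977 changed genes and a random replicate block 163, 3729 and 1783, within 1.5 times of the values without it. The fixed replicate block ended 4 of 135 named-gene calls, Igfbp2 in ΔG minus WT and Bid, Smc1b and Emcn in null minus WT (adjusted p = 0.054, 0.060, 0.062 and 0.054), with the same log2 changes. By the limit set, every same-number pair above 0.1, the numbers are not shown to pair the samples. Of 9 pairs 4 had deviations correlating above it (−0.084 to 0.27), and 6 of 9 arrays matched their own number best. That is at most a hint that some numbers mark something shared, which may or may not be a litter. No chance value was computed for it. Of 135 called named-gene values, 134 stayed called with median centring, 133 with repeated quantile normalisation, 108, 111 and 112 without WT replicate 2, null replicate 1 or WT replicate 1, and 89 with same-sex arrays. With the Y-linked covariate 77 did, 54 were lost and 4 reversed. That covariate nearly follows genotype between ΔG and null, so losses with it can come from lower precision. With 3 arrays per group, changes near the array noise are the ones these data cannot settle.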

Other observations

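The gene lists of this part, other than G1/S and G2/M, and both tests in it were chosen after the values were seen. Of 15 measured genes of a co-expressed imprinted network, 10 fell and none rose against WT, among them Dcn (log2 change −1.38, also in the matrix list), Cdkn1c (−0.82, also in the G1 list), Peg3 (−0.59), Plagl1 (−0.57) and Ndn (−0.43). The other 5, among them Igf2 (−0.095) and Mest (0.076), did not pass. None was called in ΔG against WT in limma, where camera gave the network an adjusted p of 0.28. Of 5 genes of the Dlk1-Dio3 imprinted cluster, of which Dlk1 and Meg3 are also counted in the network, 4 fell, the noncoding RNAs Meg3 (−1.03) and Rian (−0.94) and the protein genes Dlk1 (−0.80) and Rtl1 (−0.57), while Dio3 (0.23) did not pass. Camera on the network, over 4 lists, gave an adjusted p of 4.1e-07, and 0.025 with an estimated correlation. For the cluster the values were 0.0048 and 0.14. Since the network and cluster were chosen after their members were seen to fall, the 4.1e-07 cannot tell whether imprinted genes fall as a group, and body region was not tested for them. Against the WT array with high Xist alone Cdkn1c was not called (−0.67, adjusted p = 0.13), while Dcn was called in all 19 alternatives, and other members were not tested for sex.

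A hypothesis is that ΔG may raise G1/S genes by a larger share of the null change than G2/M genes. The ratio of list medians, ΔG over null, was 0.52 for G1/S and 0.24 for G2/M genes. Leaving out each array in turn gave 0.44 to 0.57 and 0.018 to 0.38, so the lowest G1/S ratio lay 0.057 above the highest G2/M ratio. With each genotype set against WT arrays of its own sex pattern, 1 array for null, the ratios were 0.55 and 0.12. The medians had been seen before, the WT arrays enter both ratios and the ranges reuse the same 9 arrays, so they show only that no 1 array makes the difference. How far cells progressed through the cycle was not measured here.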
